A study of Mus musculus with 6 samples.

How the data were processed

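PolyA-selected RNA from untreated 10T1/2 cells, a mouse embryonic fibroblast line, was sequenced from 3 wild-type (WT) libraries and from 3 libraries labelled Ranbp2 KO. The design text gives the groups as biological replicates and says that the knockout was made with CRISPR/Cas9 in the same study. Per the labels' protocols, RNA was extracted with a column kit, mRNA was captured and made into libraries with a KAPA mRNA HyperPrep kit, and the pooled libraries were sequenced on a NextSeq500. The labels do not say whether the KO-labelled libraries come from a single clone or from several, nor how the replicate cultures were separated, so the p-values measure the spread between these libraries.

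The deposited values are expected counts per gene, estimated by RSEM per the submitters' processing notes, which also name cutadapt and the genome build GRCm38. Versions, the aligner and the strand setting are not given in the sources used here. The table holds 55471 Ensembl genes, and 17.9% of its values are not whole because RSEM divides reads that match several genes. Reads of a gene and of a near-identical copy, an overlapping gene or an antisense gene may therefore have been shared, and such genes are uncertain. The mitochondrial mRNAs are in this position, since 7 annotated nuclear copies took up many of the same reads. No count of the deposited table was left out before scaling.

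Gene symbols, positions and gene types came from GENCODE M21, an annotation of the same build; 55230 identifiers matched and 241 did not, and the unmatched ones held at most 0.002% of any library's counts. Positions are 1-based GRCm38 coordinates. Total expected counts ran from 32072817 to 46321967 per library, and 24733 genes had no count in any library. Intervals and floors on ratios of counts cover counting error only, whereas the interval on the log2 difference of Ranbp2 is 1.96 SE to each side and includes the spread between libraries. The floor of a group without any count was set at 3 counts over the group.

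Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15454 genes. Libraries were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), two-sided, with genotype as the only term. P-values were adjusted by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p below 0.05. CPM values use the TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Log2 differences are KO-labelled minus WT, with the standard error (SE) taken from the F statistic. The common biological coefficient of variation was 11.5%.

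A total of 41 gene lists were fixed before the data were examined, of which 38 had at least 5 measured members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. Each list was also tested with a correlation estimated from the data and with fry, a rotation test that asks whether the members of a list move, on balance, in 1 direction without comparing them with other genes. Counts of changed members use the adjustment over all genes tested, with the counts adjusted over the list alone beside them. Some genes stand in more than 1 list. The lists cover nucleoporins, nuclear transport, the SUMO pathway, mitochondrial functions, stress responses, metabolism, the cell cycle, interferon and inflammatory genes, matrix and contractile genes, signalling targets, differentiation programmes, ribosomal proteins and markers of other cell types.

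The genes named were chosen by a rule fixed before the data were examined. Ranbp2 was given in every library. Among genes with a symbol, an adjusted p below 0.05, at least 10 CPM in the higher group and no overlap between the groups, the 12 with the largest positive and the 12 with the largest negative log2 difference were named; unnamed gene models were skipped, and 4000 genes were eligible. Of each list, up to 4 members with the smallest adjusted p were named, and of each list of another cell type the marker with the highest CPM. Genes named outside this rule are said to be so where they appear. Some members that the rule picks are not reported here.

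The analysis was tested on simulated counts drawn from the real means, library sizes and dispersions, with 15175 genes tested. For the comparison of KO-labelled with WT libraries, 64.2% of genes changed 1.5-fold, 91% of genes changed 2-fold and 100% of genes changed 4-fold were called, with 15 false calls, 8.1% of all calls. A simulated list of 25 genes raised 1.3-fold was called by camera, and 0 of 40 lists of unchanged genes were called. The simulated genes were independent, so these lists do not test the effect of correlation between genes on camera. Only 67, 67 and 66 genes were changed at 1.5-, 2- and 4-fold, and only the 25 genes of the raised list in the list simulation. In the real data 38.9% of genes were called, so the simulated rates may not carry over. Alternatives were DESeq2's size factors, library size alone, no filter, a filter of 1 CPM, DESeq2 1.42.0, limma-voom, a fold threshold of 1.5, an adjusted p of 0.01, the replicate number as a block, leaving out each library, and the other list tests. Added after the data were seen were fits without mitochondrial and abundant noncoding transcripts, without chromosomes 1, 13 and 17, or with protein-coding genes only, and list tests after subtraction of each chromosome's median or of the trend on GC content. For the level of Ranbp2, library scaling and extra copies of its region were also tested as explanations; both tests came out against them, and after that they were removed from the set weighed and are given as plain values. Figures were drawn with matplotlib.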

Results

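The comparison asked how the mRNA of 10T1/2 fibroblasts differs between WT cells and cells in which Ranbp2, the gene of a large cytoplasmic-side nuclear pore protein, was targeted with CRISPR/Cas9. The title of the series concerns contact between mitochondria and the nuclear pore complex. Each group had 3 libraries. The KO-labelled libraries held 36235615, 39378190 and 32072817 expected counts, and the WT libraries 41354198, 46321967 and 42873159. Across genes, the Pearson correlation of log2 CPM was 0.9853 to 0.9903 within groups and 0.9503 to 0.9572 between groups; genes are not independent replicates. The first principal component held 69.7% of the variance and separated the groups. No pair of libraries matched within sampling noise, so each was counted as a separate sample.

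Ranbp2 mRNA was not lower in the libraries labelled Ranbp2 KO. Ranbp2 (ENSMUSG00000003226, chromosome 10, 58446920 to 58494356, plus strand) stood at 294, 288.9 and 292.9 CPM in the KO-labelled libraries and at 219.8, 250.1 and 249.0 CPM in the WT libraries, a mean of 292 ± 2.67 against 240 ± 17.2 CPM. The log2 difference was 0.28 (95% interval 0.14 to 0.43, SE 0.07), with an adjusted p of 0.012 by edgeR. An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. The log2 difference was 0.29 with size factors from DESeq2 and 0.31 with library size alone. The 54 other genes within 5 Mb of Ranbp2 had a median log2 difference of -0.07, with 10 higher and 19 lower. On chromosome 10, at a boundary set after the data were seen, 168 genes up to 60 Mb stood at -0.28 relative to the median of all genes and 412 genes beyond it at -0.05. A count per gene does not show which exons were read, so an edited transcript that is still made would be counted as Ranbp2. The design text speaks of a complete deletion and names qPCR, western blot and staining as the assays used on it. Their values are not used here. A level that is not lower can go with an edit that leaves the transcript in place. It would not be seen if the whole gene were missing from these cells, and it does not show the deletion. For this reason the libraries are called KO-labelled, and every direction below is that of KO-labelled relative to WT libraries.

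Of 15454 genes tested, 6011 (38.9%) changed, 2721 of them higher and 3290 lower in the KO-labelled libraries. A change of at least 2-fold was found for 682 higher and 885 lower genes. Protein-coding genes accounted for 2273 of the higher and 3177 of the lower calls. The 3 values of one group lay outside the range of the other for 51.4% of genes tested, where chance gives 10%. The 2-fold count fell to 1034 when a gene had to reach 1 CPM in all 3 libraries of a group.

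The largest increase among genes that met the naming rule was that of Cytl1, a secreted protein made by chondrocytes, which rose from 0.388 ± 0.0661 to 57.2 ± 7.98 CPM, a log2 difference of 7.20 (SE 0.17). Col9a1, a collagen of cartilage, rose by 6.57 (SE 0.18) to 29.6 ± 0.391 CPM, and Sox6, a transcription factor of cartilage formation, by 4.96 (SE 0.19) to 23.4 ± 3.41 CPM. Eln, the gene of elastin, rose from 36.5 ± 5.63 to 367.2 ± 39.97 CPM, and Col8a1, a short-chain collagen, from 17.8 ± 1.48 to 161 ± 16.5 CPM. The homeobox gene Hoxc13 rose by 5.23 (SE 0.12) and Hsd11b1, an enzyme that regenerates active glucocorticoid, by 3.83 (SE 0.09). The other genes of this group were Xlr (4.96), Fry (3.90), Tspan32 (3.63), S100b (2.81) and Tinagl1 (2.77), with log2 differences in brackets. Adjusted p-values for these 12 genes lay between 4.84e-09 and 1.13e-07, and in each gene all 3 KO-labelled values lay above all 3 WT values.

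The genes with the largest decreases stood at 5.06 CPM or less in the KO-labelled libraries. Stmn2, a microtubule regulator of neurons, fell from 34.6 ± 4.65 to 0.0363 ± 0.0387 CPM, and Pxdc1 from 28.4 ± 0.737 to 0.0536 ± 0.0426 CPM. Tenm3, a teneurin cell adhesion protein, had 3 counts over the KO-labelled libraries and 2901 over the WT libraries, a ratio of 810 with a 95% counting interval of 277 to 3930. Log2 differences were -7.61 (SE 0.16) for Cemip, a hyaluronan-binding protein, -6.76 (SE 0.17) for Thy1, a surface marker of fibroblasts, and -6.66 (SE 0.12) for Sfrp1, a secreted Wnt inhibitor. Thy1 stood at 58.3 ± 2.45 CPM in WT and 0.534 ± 0.216 CPM in KO-labelled libraries, and Sfrp1 at 129 ± 9.77 and 1.26 ± 0.183 CPM. Npy1r, a neuropeptide Y receptor, fell from 146 ± 9.96 to 5.06 ± 0.362 CPM. Pde3b fell by 6.60, Tmtc1 by 5.02, Mark1 by 4.76, Igsf10 by 4.71 and Selp, the gene of P-selectin, by 4.42 on the log2 scale. Adjusted p-values lay between 3.48e-09 and 4.71e-08, and in each gene all 3 KO-labelled values lay below all 3 WT values.

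**Figure D1:**
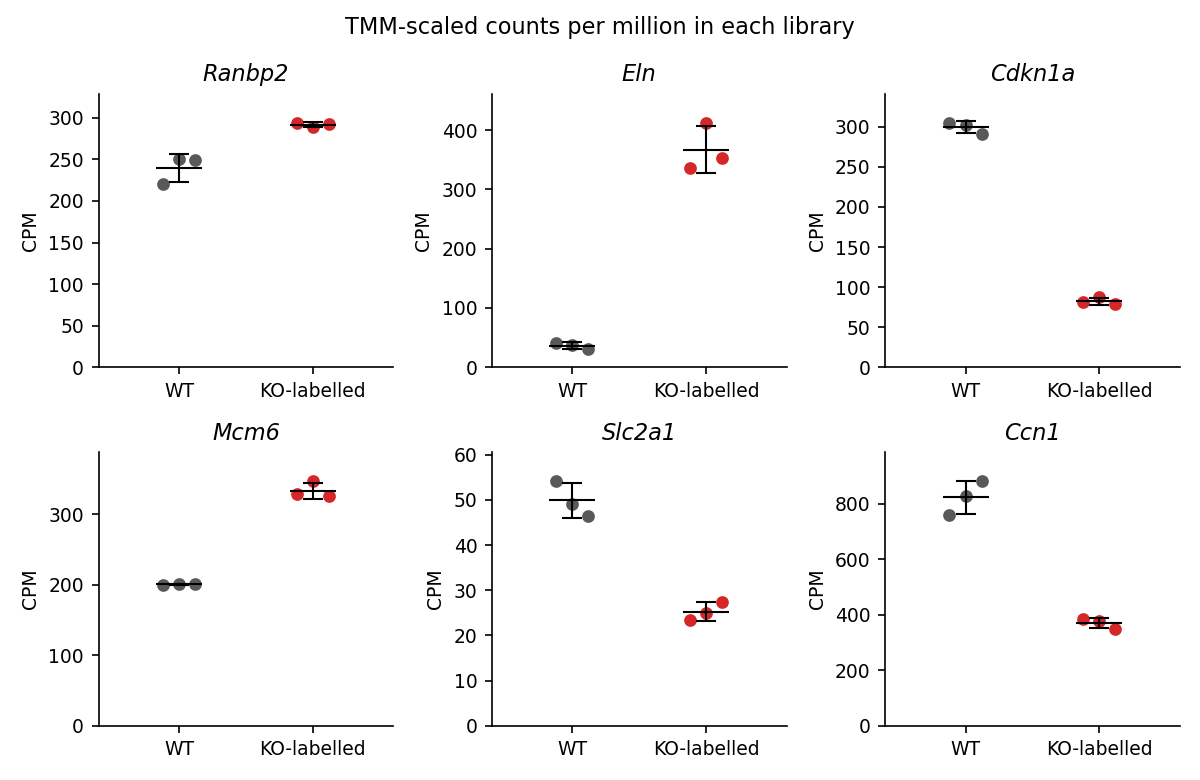
TMM-scaled CPM (vertical axis, from 0) of 6 of the named genes, picked after their values were seen, in each WT library (grey points) and each KO-labelled library (red points); horizontal bars are means and whiskers 1 SD, n = 3 per group. Ranbp2, Eln and Mcm6 lie higher and Cdkn1a, Slc2a1 and Ccn1 lower in the KO-labelled libraries, without overlap between groups.

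Camera called 13 of the 38 lists tested, 4 higher and 9 lower in the KO-labelled libraries. With a correlation estimated for each list it called 0 lists at an adjusted p below 0.05, and 8 lists had an unadjusted p below 0.05; fry called 22 lists, 11 of them among the 13.

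**Figure D2:**
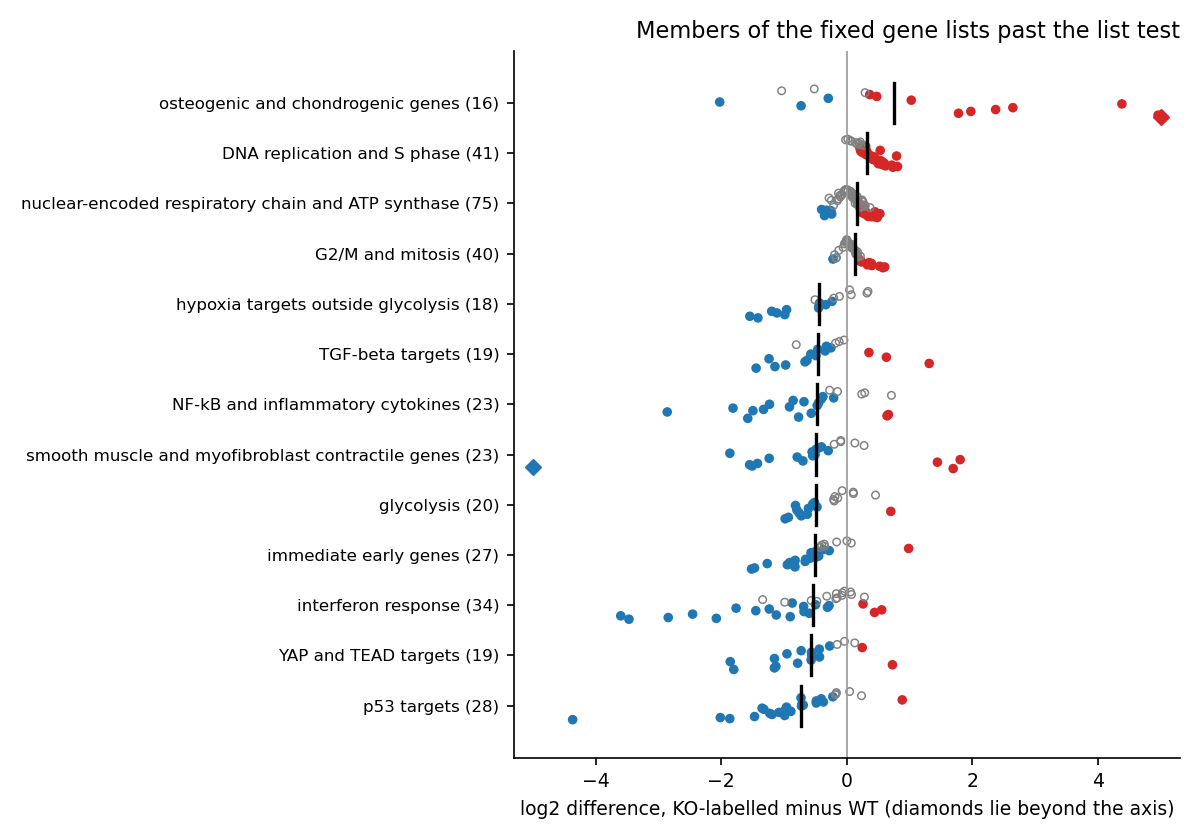
Log2 difference, KO-labelled minus WT (horizontal axis), of each measured member of the 13 lists called by camera, with the number of members in brackets. Filled points passed the gene test (red higher, blue lower), open points did not, diamonds lie beyond the axis and black bars are list medians, which run from -0.73 for p53 targets to 0.75 for osteogenic and chondrogenic genes.

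Targets of p53 fell. Of 28 measured members, 22 fell, 1 rose and 5 did not pass, or 22 and 2 adjusted over the list alone, with a median log2 difference of -0.73 and a camera adjusted p of 2.95e-08 (adjusted p = 0.105 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, fell from 300 ± 7.26 to 82.4 ± 4.37 CPM, a log2 difference of -1.86 (SE 0.07). Perp, a desmosome-associated membrane protein, fell from 23.7 ± 0.426 to 1.14 ± 0.261 CPM, Eda2r from 68.5 ± 6.10 to 16.96 ± 0.632 CPM, and Btg2, an antiproliferative gene that is also in the immediate early list, from 35.3 ± 3.33 to 12.8 ± 0.697 CPM. Ddb2, a DNA damage recognition protein, was the member that rose and was named after its value was seen.

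Genes of DNA replication and S phase rose: 31 of 41 rose, 0 fell and 10 did not pass, or 32 and 0 adjusted over the list alone. The median was 0.31 and the camera adjusted p 1.73e-08 (adjusted p = 0.161 with an estimated correlation). Mcm6, a subunit of the replicative helicase, rose from 200.4 ± 0.780 to 333 ± 11.4 CPM, and Uhrf1, which recruits DNA methyltransferase to replicated DNA, from 151 ± 13.1 to 264 ± 16.7 CPM. Chaf1b, of the chromatin assembly factor, rose by 0.61 (SE 0.07) and Rfc3, of the clamp loader, by 0.72 (SE 0.09) on the log2 scale. Of 40 genes of G2/M and mitosis, 12 rose, 1 fell and 27 did not pass, or 10 and 0 adjusted over the list alone; the median was 0.13 and the camera adjusted p 0.0218 (adjusted p = 0.787 with an estimated correlation). Cdc25c, a phosphatase that activates Cdk1, rose by 0.57 (SE 0.07) and Pttg1, the gene of securin, by 0.60 (SE 0.08). The call for this list was lost without KO-labelled library 2 (adjusted p = 0.162) or WT library 2 (0.0892) and without a count filter (0.104), in a range of 0.000529 to 0.162 over the alternatives that kept the preset correlation.

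Glycolytic genes fell. Of 20 members, 11 fell, 1 rose and 8 did not pass, with the same numbers adjusted over the list alone, a median of -0.49 and a camera adjusted p of 0.00267 (adjusted p = 0.382 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell from 49.9 ± 3.88 to 25.3 ± 2.06 CPM, and Ldha, a subunit of lactate dehydrogenase, from 992 ± 29.3 to 600.0 ± 39.7 CPM. Pfkl fell by 0.93 (SE 0.09) and Pgam1 by 0.63 (SE 0.07) on the log2 scale. Hypoxia targets outside glycolysis fell in 11 of 18 cases, with 0 higher and 7 not passing, or 12 and 0 adjusted over the list alone, a median of -0.44 and a camera adjusted p of 0.000561 (adjusted p = 0.161 with an estimated correlation). Ndrg1 fell from 49.8 ± 4.42 to 18.7 ± 0.369 CPM, and P4ha1, a collagen prolyl hydroxylase, from 216.1 ± 11.97 to 109 ± 6.21 CPM. Ddit4, an inhibitor of mTORC1 that is also in the ATF4 list, fell by 1.54 (SE 0.11).

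Immediate early genes fell: 19 of 27 fell, 1 rose and 7 did not pass, or 20 and 1 adjusted over the list alone, with a median of -0.50 and a camera adjusted p of 1.73e-06 (adjusted p = 0.161 with an estimated correlation). Maff fell from 40.4 ± 3.24 to 14.1 ± 1.08 CPM, and the AP-1 subunit Fosl2 from 169 ± 5.39 to 95.7 ± 3.23 CPM. Targets of YAP and TEAD fell in 14 of 19 cases, with 2 higher and 3 not passing, the same numbers adjusted over the list alone, a median of -0.56 and a camera adjusted p of 0.000561 (adjusted p = 0.251 with an estimated correlation). Ccn1, a matricellular protein, fell from 824 ± 60.6 to 370 ± 18.0 CPM, and F3, the gene of tissue factor, from 276 ± 43.5 to 79.3 ± 10.6 CPM, while Tgfb2 rose by 0.73 (SE 0.07). Targets of TGF-beta fell in 12 of 19 cases, with 3 higher and 4 not passing, the same numbers adjusted over the list alone, a median of -0.46 and a camera adjusted p of 0.0086 (adjusted p = 0.161 with an estimated correlation). Ltbp1, a latent TGF-beta binding protein, fell by 1.44 (SE 0.09) and Pmepa1 by 1.14 (SE 0.08), while Bambi, a pseudoreceptor that dampens TGF-beta signalling, rose by 1.31 (SE 0.12).

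Interferon response genes fell in 17 of 34 cases, with 3 higher and 14 not passing, or 18 and 3 adjusted over the list alone. The median was -0.53 and the camera adjusted p 0.000465 (adjusted p = 0.161 with an estimated correlation). Many were weakly expressed: Gbp2, a guanylate-binding protein, fell from 6.16 ± 1.19 to 0.554 ± 0.0186 CPM and Tap1, a peptide transporter of antigen presentation, from 8.38 ± 0.578 to 1.99 ± 0.241 CPM. Irf9, a transcription factor of the interferon pathway, fell by 0.90 (SE 0.08). NF-kB and inflammatory cytokine genes fell in 16 of 23 cases, with 2 higher and 5 not passing, the same numbers adjusted over the list alone, a median of -0.47 and a camera adjusted p of 0.00358 (adjusted p = 0.161 with an estimated correlation). Csf1, a macrophage growth factor, fell from 630 ± 15.9 to 370 ± 13.8 CPM and the chemokine Ccl7 from 9.02 ± 1.23 to 3.03 ± 0.263 CPM. Sod2, the mitochondrial superoxide dismutase, and Vcam1, an adhesion molecule, were the members that rose, by 0.64 (SE 0.06) and 0.66 (SE 0.07).

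Smooth muscle and myofibroblast contractile genes fell in 15 of 23 cases, with 3 higher and 5 not passing, or 15 and 4 adjusted over the list alone. The median was -0.49, also with Itga8 set to its bound, and the camera adjusted p 0.00376 (adjusted p = 0.533 with an estimated correlation). Itga8, an integrin subunit, had 0 counts over the KO-labelled libraries and stood at 8.03 ± 0.874 CPM in WT libraries, at least 291-fold lower against the floor of 3 counts over the group. The tropomyosin gene Tpm2 fell from 229 ± 20.8 to 80.61 ± 4.004 CPM and the myosin light chain gene Myl9 from 201 ± 15.2 to 68.7 ± 5.78 CPM. Actg2, an actin of visceral smooth muscle, rose from 70.3 ± 5.29 to 228 ± 9.74 CPM.

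Osteogenic and chondrogenic genes rose: 10 of 16 rose, 3 fell and 3 did not pass, or 11 and 3 adjusted over the list alone, with a median of 0.75 and a camera adjusted p of 0.00704 (adjusted p = 0.161 with an estimated correlation). Beside Col9a1 and Sox6, Spp1, the gene of osteopontin, rose from 68.9 ± 4.07 to 236 ± 18.1 CPM, and the cartilage collagen gene Col11a1 from 130.1 ± 2.66 to 511 ± 58.6 CPM. Runx2, Sox9 and Msx2, transcription factors of bone and cartilage formation, were the members that fell and were named after their values were seen. Fibroblast extracellular matrix genes moved in both directions, with 11 of 35 higher, 15 lower and 9 not passing, the same numbers adjusted over the list alone. The median was -0.06, the mean 0.18 and the test pointed down (camera adjusted p 0.806). Postn, the gene of periostin, rose from 309 ± 18.9 to 1165 ± 88.5 CPM and the collagen VI gene Col6a3 from 323 ± 31.4 to 1554 ± 289 CPM. Among members that fell, named after their values were seen, Thbs1, the gene of thrombospondin 1, went from 2189 ± 372 to 591 ± 61.5 CPM and the collagen XII gene Col12a1 from 810.5 ± 10.95 to 288 ± 51.4 CPM. Of 15 basement membrane genes, 3 were higher and 8 lower, the same numbers adjusted over the list alone (camera adjusted p 0.124, but 0.0244 under 1 of 14 alternatives). Lama2, a laminin chain, fell from 5.64 ± 0.263 to 0.219 ± 0.0368 CPM, Nid1, the gene of nidogen, by 0.91 (SE 0.09), and Col18a1 rose by 1.34 (SE 0.14).

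Adipogenic genes split, with 8 of 14 higher and 5 lower, the same numbers adjusted over the list alone. The median was 0.32, the mean -0.04 and the test pointed up (camera adjusted p 0.521). Lpl, the gene of lipoprotein lipase, rose from 3.72 ± 0.436 to 20.5 ± 1.46 CPM and Fabp4, a fatty acid binding protein, from 8.02 ± 1.82 to 27.5 ± 2.51 CPM, while Dlk1, an inhibitor of adipogenesis, fell from 9.49 ± 1.86 to 0.718 ± 0.121 CPM and Cebpa, a driver of it, from 5.56 ± 1.121 to 1.13 ± 0.143 CPM. Of 9 skeletal muscle genes, 4 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p 0.217), with Tnnt2, a cardiac troponin, 1.31 higher (SE 0.16) and the transcription factor gene Pax3 3.95 lower (SE 0.43) on the log2 scale.

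Other nucleoporins moved in both directions by small amounts: 7 of 28 were higher, 6 lower and 15 did not pass, or 7 and 7 adjusted over the list alone (camera adjusted p 0.844). The mean was -0.003, the median lay just above 0 and the test pointed up. Nup155, a scaffold nucleoporin, rose from 108 ± 3.84 to 141 ± 2.80 CPM and Tpr, of the nuclear basket, from 303 ± 20.0 to 398 ± 27.6 CPM, while Nup153, also of the basket, fell from 141 ± 12.1 to 108 ± 4.81 CPM. Of 31 nuclear transport receptors and Ran cycle genes, 6 were higher and 3 lower, or 5 and 3 adjusted over the list alone (camera adjusted p 0.517). Ipo13, an import receptor, fell by 0.68 (SE 0.10) and Kpna4, an importin alpha, rose by 0.36 (SE 0.08). Their median was 0.06, their mean -0.004 and the test pointed up. Of 16 SUMO pathway genes, 1 was higher and 4 lower, the same numbers adjusted over the list alone (camera adjusted p 0.876), with a median of 0.01, a mean of -0.02 and a test that pointed down. Sumo3 fell from 97.5 ± 6.40 to 70.3 ± 3.58 CPM.

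The list of nuclear-encoded genes of the respiratory chain and ATP synthase was called higher, although most members did not pass the gene test. Of 75 members, 21 rose, 5 fell and 49 did not pass, or 20 and 5 adjusted over the list alone, with a median of 0.17 and a camera adjusted p of 0.0086 (adjusted p = 0.787 with an estimated correlation). The complex I genes Ndufs1 and Ndufb10 rose, Ndufs1 from 99.3 ± 5.39 to 139 ± 7.20 CPM and Ndufb10 from 44.6 ± 3.97 to 61.3 ± 1.24 CPM. Ndufs1 lies on chromosome 1 and Ndufb10 on chromosome 17, where genes stood 0.29 and 0.26 higher in median than all genes. The list was still called after subtraction of each chromosome's median. Without KO-labelled library 2 this call was lost (adjusted p = 0.11), as it was without a count filter (0.0519), in a range of 0.000144 to 0.11 over the alternatives that kept the preset correlation. Mitochondrially encoded mRNAs stood higher in median by 0.49 on the log2 scale, with 4 of 13 past the gene test, 0 lower and 9 not passing, the same numbers adjusted over the list alone (camera adjusted p 0.0599, range 0.00285 to 0.864 over alternatives). The highest of these 4 by mean was mt-Co1, a subunit of cytochrome c oxidase, at 13920 ± 2132 against 9679 ± 1602 CPM. The calls of mt-Co1, mt-Nd5, mt-Nd6 and mt-Atp6 were each lost without KO-labelled library 2, KO-labelled library 3, WT library 1 or WT library 2; for mt-Co1 the adjusted p was then 0.0931, 0.0942, 0.0846 and 0.0933. These mRNAs share reads with nuclear copies: the expected count of mt-Co3, named after its values were seen, was 0.25 in WT library 1 and 4694.47 in WT library 2. Summed with 7 such copies they took 57869 ± 10110 CPM in KO-labelled and 45373 ± 10286 CPM in WT libraries, and an exact two-sided permutation test gave p = 0.2.

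Other mitochondrial lists were not called. Mitochondrial fatty acid oxidation had 9 of 20 genes higher and 3 lower, the same numbers adjusted over the list alone, a median of 0.17 and a camera adjusted p of 0.063 (range 0.0166 to 0.162 over alternatives). Acadl and Acsl1, of long-chain fatty acid breakdown and activation, rose by 0.61 (SE 0.08) and 0.51 (SE 0.07), and the carnitine carrier gene Slc25a20 fell by 0.94 (SE 0.09). Mitochondrial ribosomal protein genes were higher in 15 and lower in 10 of 78 cases, or 14 and 10 adjusted over the list alone (camera adjusted p 0.546), with Mrps27 0.73 lower (SE 0.08) and Mrps9 0.47 higher (SE 0.09). Of 23 genes of the TCA cycle and pyruvate dehydrogenase, 3 were higher and 2 lower, or 3 and 1 adjusted over the list alone (camera adjusted p 0.517), with Fh1, the gene of fumarase, 0.41 higher (SE 0.06). Of 27 protein import genes, 2 were higher and 2 lower, or 0 and 2 adjusted over the list alone (camera adjusted p 0.876, median 0.009, mean -0.009, test pointing down), with Tomm40, the outer membrane channel, 0.46 lower (SE 0.09). Of 27 genes of mitochondrial dynamics and organelle contacts, 4 were higher and 3 lower, or 4 and 2 adjusted over the list alone (camera adjusted p 0.805, median -0.001, mean 0.05, test pointing up). Itpr1, a calcium channel of the endoplasmic reticulum, rose from 14.99 ± 0.0992 to 43.6 ± 4.06 CPM.

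Among 16 regulators of mitochondrial biogenesis, 3 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p 0.517). Ppargc1a, the coactivator PGC-1alpha, rose from 0.274 ± 0.0873 to 6.46 ± 0.638 CPM and Ppargc1b from 0.331 ± 0.0813 to 1.77 ± 0.265 CPM, whereas Esrra, a nuclear receptor partner of both, fell from 19.2 ± 1.88 to 10.5 ± 0.703 CPM. Of 9 calcium uptake genes, 0 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p 0.417, median 0.01, mean -0.27, test pointing down). The uniporter gene Mcu fell from 50.5 ± 4.34 to 36.03 ± 1.121 CPM and Mcub, its inhibitory paralog, from 13.7 ± 0.827 to 4.94 ± 0.408 CPM.

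Stress response lists were not called by camera in the fit reported. Of 33 targets of ATF4 and the integrated stress response, 8 rose and 12 fell, or 9 and 12 adjusted over the list alone (camera adjusted p 0.426, but 0.0321 without a count filter), with Vldlr, a lipoprotein receptor, falling from 39.7 ± 1.89 to 12.3 ± 0.641 CPM and Gdf15, a stress-induced cytokine, from 1.43 ± 0.319 to 0.146 ± 0.0160 CPM. Of 12 genes of the mitochondrial unfolded protein response, 4 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p 0.377), with the chaperonin gene Hspe1 0.49 higher (SE 0.11). Of 21 genes of the endoplasmic reticulum unfolded protein response, 7 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p 0.0772, but called under 3 of 14 alternatives, at 0.0386 without WT library 3), with Sec61b 0.40 higher (SE 0.08). Of 20 NRF2 targets, 5 rose and 5 fell, or 6 and 6 adjusted over the list alone (camera adjusted p 0.864), with the ferritin light chain gene Ftl1 0.48 higher (SE 0.10) and Txnrd1, a thioredoxin reductase, 0.32 lower (SE 0.06). Of 20 heat shock and chaperone genes, 2 rose and 4 fell, or 1 and 4 adjusted over the list alone (camera adjusted p 0.844, median 0.02, mean -0.32, test pointing down), with Hspb1 falling from 2.36 ± 0.184 to 0.118 ± 0.0195 CPM. Of 24 cholesterol biosynthesis genes, 3 rose and 6 fell, or 3 and 7 adjusted over the list alone (camera adjusted p 0.377). Of 12 calcineurin and NFAT genes, 2 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p 0.521), with Nfatc1 1.06 higher (SE 0.08) and Nfatc4 1.36 lower (SE 0.16). Of 54 cytosolic ribosomal protein genes, 5 rose and 1 fell, or 0 and 0 adjusted over the list alone (camera adjusted p 0.59, but 0.00989 under 1 of 14 alternatives).

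Markers of other cell types were mostly weak. Of 6 endothelial markers, 2 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p 0.54), and the most abundant, Tek, stood at 21.9 ± 1.88 CPM in KO-labelled and 37.1 ± 2.41 CPM in WT libraries. Of 8 neural and glial markers, 2 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p 0.876, median 0.33, mean -1.07, test pointing up). Map2, the most abundant, rose from 177 ± 8.05 to 271 ± 10.8 CPM, whereas Tubb3, a neuronal tubulin, fell from 15.4 ± 1.10 to 2.03 ± 0.207 CPM. The epithelial, immune and pluripotency lists had 1, 4 and 2 measured members and were not tested. Their most abundant markers, in CPM by library size alone, were Cdh1 at 7.48 in KO-labelled and 2.21 in WT libraries, Cd14 at 2.717 and 5.997, and Klf4, which fibroblasts also express, at 267 and 250.1.

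The change in expression also differed by chromosome. Over 11346 protein-coding genes with a mean of at least 1 CPM, the median log2 difference was -0.03. Relative to it, the 643 genes of chromosome 1 stood 0.29 higher in median, the 560 genes of chromosome 17 stood 0.26 higher and the 433 genes of chromosome 13 stood at -0.33. On chromosome 1, 324 genes rose and 66 fell; on chromosome 17, 247 rose and 61 fell; on chromosome 13, 14 rose and 261 fell. These 3 chromosomes were singled out after the data were seen, as the largest shifts. Smaller ones were -0.18 on chromosome 9, -0.17 on chromosome 19, 0.15 on chromosome 6, 0.14 on chromosome 18, 0.13 on chromosome 4 and -0.13 on chromosome 10, where the part up to 60 Mb that holds Ranbp2 stood at -0.28, further from 0 than chromosome 17. Without chromosomes 1, 13 and 17, 4765 of 13058 genes changed, 1950 of them higher and 2815 lower. The differences given above for single genes were not corrected for these shifts. Among the genes that moved with their chromosome were Ndufs1, Mrps9, Hspe1, Col9a1, Col6a3, Mcm6, Map2, Tgfb2 and Tnnt2 on chromosome 1. Ndufb10 and Uhrf1 on chromosome 17 did so too, as did Mrps27, Nid1 and Msx2 on chromosome 13. Pax3 on chromosome 1 and Ltbp1 and Runx2 on chromosome 17 moved against their chromosome. Not every named gene on these chromosomes is listed here.

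**Figure D3:**
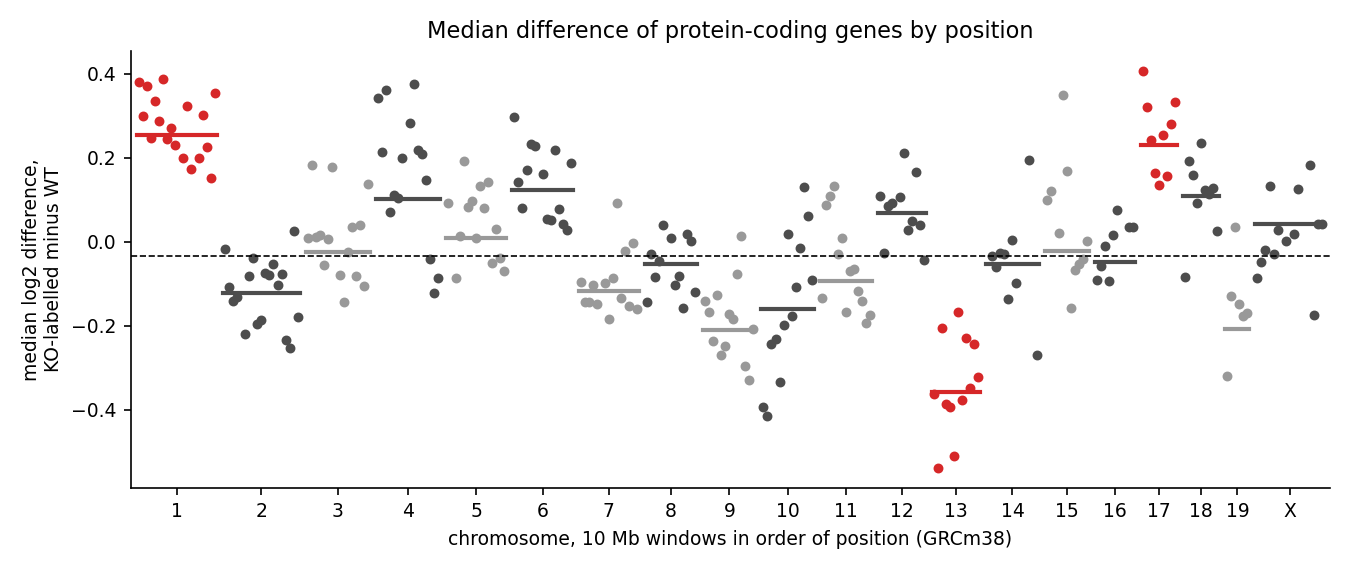
Median log2 difference, KO-labelled minus WT (vertical axis), of protein-coding genes in 10 Mb windows with at least 10 genes, in order of position along 20 chromosomes (horizontal axis, GRCm38). Points are windows, solid lines chromosome medians and the dashed line the median of all genes, -0.03; chromosomes 1, 13 and 17 are in red, and each of their 39 windows lies on the same side of the dashed line as its chromosome.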

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

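The fits without chromosomes 1, 13 and 17, without mitochondrial and abundant noncoding transcripts or with protein-coding genes only, and the list tests after subtraction of chromosome medians or the GC trend, were chosen after seeing the data. Across the other scalings, filters, tools and added fits, the number of changed genes ran from 4765 to 6652 (6011 as reported), and Ranbp2 stayed higher and called at 0.25 to 0.31. Requiring 1 CPM in all 3 libraries of a group lowered the 2-fold count to 1034, with 12567 genes tested. A test against a 1.5-fold change called 1494 genes, 533 higher and 961 lower, and an adjusted p below 0.01 called 3784, with 1543 higher; both are stricter by construction. Scaling by library size alone moved the share of higher calls from 45.3% to 48.8%.

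Of the 38 lists, 13 were called with the preset correlation, 0 with an estimated correlation and 22 by fry, which also turned the neural and glial list from up to down at its mean of -1.065; the cause was not tested. With the preset correlation, 11 of the 13 calls held under each of 14 alternatives, at adjusted p-values of up to 0.0212. Lists gained were the mitochondrially encoded one under 6 of 13, fatty acid oxidation under 5 of 14, the endoplasmic reticulum response under 3, and ATF4 targets (0.0321), basement membrane (0.0244) and cytosolic ribosomal proteins (0.00989) under 1 each. Leaving out each library gave 4353 to 6106 genes, of which 1839 to 2737 were higher, 2514 to 3369 lower and 1482 to 1632 at least 2-fold, 11 to 16 lists, and 0.22 to 0.31 for Ranbp2. Of 174 other named genes, up to 19 lost their call in such a fit and none reversed. With the replicate number as a block 4994 genes were called; same-numbered libraries correlated at 0.022, -0.081 and -0.034, so the numbers do not pair the samples. TPM was not used here, since the table holds counts only. Depth limits genes of a few counts, for which ratios have wide intervals.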

Other observations

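The tests of this part on GC content, gene length and the spread within groups for chromosomes were set before their results were seen, and the others after. The genes in this paragraph were chosen after their values were seen. All 7 tested genes of the Hoxc cluster on chromosome 15 rose in the KO-labelled libraries, of 9 annotated. Hoxc13 was the most abundant, and Hoxc9 rose from 0.146 ± 0.0472 to 5.57 ± 0.235 CPM and Hoxc6 from 0.0988 ± 0.0524 to 0.540 ± 0.182 CPM (n = 3 per group). Hoxc11 had 245 counts over the KO-labelled and 1 over the WT libraries, a ratio of 292 with a 95% counting interval of 52 to 11600. Hotair, a noncoding RNA transcribed from this cluster, had 0 counts over the WT libraries and 0.756 ± 0.122 CPM in KO-labelled libraries, at least 32.6-fold higher against the floor of 3 counts over the group. Of 9 tested Hoxa genes, 2 rose and 1 fell, and no Hoxb or Hoxd gene was expressed enough to be tested.

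In the tested set, 29 genes had 0 counts over the KO-labelled libraries and 2 genes, Hotair and Mageb16, had 0 over the WT libraries. After Itga8, the most abundant in WT libraries was Sall1, a zinc finger transcription factor, at 6.04 ± 0.422 CPM and at least 219-fold lower in KO-labelled libraries. Khdrbs3, an RNA-binding protein, stood at 4.31 ± 0.572 CPM in WT libraries and was at least 156-fold lower. The set also holds the developmental regulators Gsc, Tbx20 and Nog.

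Ranbp2 mRNA stood 1.22-fold higher in the KO-labelled libraries. A single mislabelled library would correlate better with the other group, but the highest correlation between groups was 0.957 and the lowest within a group 0.985. An exchange of the labels of whole groups cannot be told apart from correct labels by this gene, since a ratio of 1.22 is neither a loss in WT libraries nor a loss in KO-labelled ones. Reads shared with other genes stay open as well, although only 1 of 6 libraries had an expected count of Ranbp2 that was not whole, against 47.9% of nonzero values over tested genes. An edited transcript that escapes decay may also give these counts and was not tested.

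Chromosomes 1, 13 and 17 had the largest of several chromosome shifts. After removal of the trend on GC content the smallest of the 3 shifts was 0.257, and after removal of the trend on exon length 0.265. From the 5th to the 95th percentile of genes the GC trend spanned 0.362 log2 and the length trend 0.102. The length trend was thus too small to give these shifts, and its removal could hardly have taken them away. Neither trend accounts for them. Between libraries of one group the largest shift of these chromosomes was 0.112, below the smallest of the 3, 0.261. A different number of copies of these chromosomes in the cell populations is a candidate explanation. Of 39 windows of 10 Mb, 100% lay on their chromosome's side of the genome median, which was also so for 14 of 14 windows of chromosome 6. The 3 chromosomes were picked for their shifts, and 80.5% to 84.3% of their genes lay on that side, so this outcome was likely in advance. It does not tell copy number from another shift of a whole chromosome. Copy number itself was not measured, and the effect of genotype and that of clonal history were not separated.

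The fall of p53 targets remained under technical corrections but was smaller after removal of the GC trend. The list median of -0.73 was -0.70 under the scaling that moved it most and -0.69 after subtraction of each chromosome's median. After removal of the GC trend it was -0.58. The GC trend spanned 0.362 log2 from the 5th to the 95th percentile of genes. The chromosome median furthest from 0 was -0.358, on chromosome 13, and the TMM factors ran from 0.9766 to 1.0577. Corrections of this size could hardly have removed the fall of the list, so the outcome was likely in advance. The values show only that scaling, chromosome position and GC content, as measured here, are each too small to be the whole cause. Trp53 itself, a list member named after its value was seen, fell by 0.37 on the log2 scale (SE 0.07). A genotype effect and a clonal difference in the p53 pathway may each give this pattern, and the design does not separate them.

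The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 6011 genes by edgeR, as the only 1 of the 10 with so many, and the highest of the others 0, with up to 394 genes at an unadjusted p below 0.05 and up to 3 genes by limma-voom. Every other split mixes both groups on each side, so the group difference adds to the spread within its sides. Few gene calls there were therefore likely in advance, and no conclusion is drawn from them. For the fixed lists the real split gave 13 calls by camera and the highest of the others also 13, so 2 splits gave as many. Each of the others gave at least 4 list calls with 0 genes changed, although each of these splits still carries part of the group difference.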
